A study of Delphinium anthriscifolium with 89 samples.

How the data were processed

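RNA sequencing was carried out on total RNA from organs of *Delphinium anthriscifolium*, extracted with the RNAprep Pure Plant Kit from TIANGEN and made into libraries with the Fast RNA-seq Lib Prep Kit V2, per the labels' protocols. The submitters' processing notes name TopHat2 and RSEM, without versions or roles. The reference, the annotation, the strandedness and any read filter are not given in the sources used here. The feature IDs have the form of transcripts of a de novo assembly with predicted reading frames. The deposited values are estimated counts per feature, not normalized: the columns hold between 93.2% and 99.2% whole numbers and sum to different totals. All 89 files list the same 32115 features in the same order, and 3816 of them are at 0 in every library. These features belong to 26584 assembly genes as the ID names them, and 29.3% of features lie in an assembly gene with more than 1 feature. Near-identical features can share reads, which RSEM divides between them by estimation, so the value of a single feature of such a gene is uncertain. Where a kit or count does not separate strands, transcripts from overlapping genes on opposite strands cannot be separated either.

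Groups were taken from the sample titles. The files carry IDs without gene names, and no table of names was used, so lists of genes by name that had been planned were not analysed here. Named features were chosen by a rule written before the data were examined, as were the comparisons, their tests and most alternatives. Per comparison of petal types at a stage and for ans-lmi1 against ans, the rule takes the 2 highest and 2 lowest log2 fold changes among features with adjusted p under 0.05, a mean of at least 1 CPM and no overlap between the groups. For organ-enriched sets it takes the 2 most abundant members, and where a comparison calls 5 features or fewer in a direction each is named. Features counted within a set are not named.

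Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F tests (robust) on TMM-scaled libraries after filterByExpr. Each family of libraries was fitted separately with one mean per group: 22 petal libraries (21834 features tested), 33 sepal libraries (21673), 8 leaf and bract libraries (18368) and 4 silencing libraries (18757). The biological coefficient of variation common to all features was 0.47 in petals, 0.72 in sepals, 0.3 in leaves and bracts and 0.27 in the silencing libraries. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The SE of a log2 fold change was taken as its size divided by the square root of F. Dorsal sepals were compared with the mean of lateral and ventral sepals. The change of the petal difference with stage was tested with one F test over 3 differences between stages. CPM values of single features use the TMM factors of the fit they come from, and those of organ sets and silencing libraries come from all libraries scaled together. The level of a feature in an organ is the mean over its groups. Log2 CPM values use a prior count of 2. Where a group had no counts, the fold is given as at least the ratio to a floor of 3 counts over the group, and with 1 to 3 counts as a ratio with its exact 95% counting interval.

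Organ-enriched features were required to be at least 4-fold above each other organ kind, and lateral-petal-enriched features at least 2-fold above dorsal petals and each other kind, each with adjusted p under 0.05 in a fit of all 85 wild-type libraries. Feature sets were tested with limma 3.58.1, by camera with a preset correlation of 0.01, again with an estimated correlation, and by fry, with Benjamini-Hochberg adjustment over 60 tests in petals and 11 in the silencing libraries. Alternatives were DESeq2 1.42.0, no filter on low counts, the replicate number as a block, other choices of libraries sharing the spread, leaving out each replicate, another kind of correlation and another set rule. Chosen after the data were seen were fits without the libraries under 19000 features, limma voom with sample quality weights, petal libraries thinned to the smallest total, and a developmental score as a covariate in the silencing fit.

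Replicate libraries of one group were compared by chi-square over features with a summed count of 20 or more. The lowest chi-square per feature was 6.11, so no pair agreed within sampling noise, and log2 CPM values within a group correlated between 0.67 and 0.986 (median 0.947). Groups share replicate numbers in the labels, which do not say what a number marks. Whether numbers pair the libraries was checked from the correlation of deviations from group means. With 3 or more pairs, all above 0.1, they did for dorsal against lateral petals at S10 (0.16 to 0.32) and S16 (0.2 to 0.35), for dorsal against non-spurred sepals at S10 (0.1 to 0.37), S12 (0.4 to 0.46) and S16 (0.13 to 0.41), for lateral against ventral sepals at S10 (0.13 to 0.33), S12 (0.48 to 0.55) and S16 (0.16 to 0.27), and for leaves against bracts (0.11 to 0.49).

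The procedure was tested on simulated counts drawn from the means and sizes of the real libraries with 200 features changed. Changed features had a mean count of 20 or more. All groups had one mean before the change, replicate numbers had no structure, and outside the organ simulation the dispersions were edgeR's own. The rates below therefore do not cover changes in sparse features or the structure of the real libraries. In dorsal against lateral petals at S12 (21834 features), edgeR recovered 4.5%, 47.8% and 69.7% of the features changed by 2-fold, 4-fold and 8-fold, with 1.2% false calls. At S9 with 2 libraries a group it recovered 0%, 37.3% and 63.6% with 4.3% false calls. In dorsal against non-spurred sepals at S12 (21673 features) it recovered 6%, 29.9% and 60.6% with 1.5% false calls, in leaves against bracts (18368 features) 19.4%, 85.1% and 95.5% with 5%, and in the silencing comparison (18757 features) 23.9%, 70.1% and 93.9%. In that simulated comparison 20.9% of edgeR's calls were false, above the nominal 5%. DESeq2 gave 19.9%, 23.3%, 20.5%, 18.7% and 27.7% false calls in these 5 comparisons in the same order. For the change of the petal difference with stage edgeR recovered 0%, 35.8% and 60.6% with 5.9% false calls. Of 200 features raised 16-fold among 3000 in a simulated organ, a larger change than the 4-fold of the rule, all 200 entered its set. In a further simulation camera called the raised set and 0 of 20 random sets. Features were drawn independently there, so camera with the preset correlation was not tested on sets whose members vary together. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.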

Results

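Transcript counts were measured by RNA sequencing in 89 libraries from *Delphinium anthriscifolium*, a larkspur in the buttercup family. Its flowers have a spurred dorsal sepal and a pair of spurred dorsal petals beside non-spurred lateral petals. The 85 wild-type libraries fell into 30 groups: leaves and bracts with 4 libraries each, and 3 sepal types, 2 petal types, stamens and carpels at the floral stages S9 (2 libraries a group), S10, S12 and S16 (3 libraries a group). A further 4 libraries came from a silencing experiment, 2 titled ans and 2 titled ans-lmi1. Library totals ran from 4201867 to 22100119 estimated counts with a median of 8555603, and between 9879 and 23305 of the 32115 features had a count in a library (median 21599). A count of 3 in 1 library corresponded to between 0.136 and 0.714 CPM, which are counts scaled to a common library total. In 21 libraries fewer than 19000 features were detected, of which 4 were petal, 10 sepal and 7 stamen or carpel libraries. All 7 libraries of replicate 3 at S16, from several of these organs, were among the 21. The files do not pair the feature IDs with gene names, so features are named by ID, with few IDs per comparison. Nothing in the labels says that replicates came from separate plants, so p-values measure the spread between these libraries, which may be technical. Intervals and floors cover counting error only.

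The design centres on how the dorsal spurred petals and the lateral non-spurred petals differ as the flower develops. At S10, 51 features were higher in dorsal petals and 72 were higher in lateral petals, 123 in all among 21834 tested. DN37984_c0_g1_i1|m.21038 was at 9.24 ± 3.1 CPM (SD, n = 3) in dorsal petals and at 0 counts in the 3 lateral libraries, at least 63.9-fold higher (edgeR quasi-likelihood adjusted p = 0.0198). DN17121_c0_g1_i1|m.4086 was at 4.91 ± 0.591 CPM in dorsal petals and 0 in lateral ones, at least 33.7-fold higher (edgeR adjusted p = 0.018). In the other direction, DN40207_c0_g1_i1|m.27337 was at 5.84 ± 1.91 CPM in lateral petals and 0 in dorsal ones, at least 91.8-fold lower in dorsal petals (edgeR adjusted p = 0.0198), and DN39067_c0_g1_i3|m.23598 was at 9.02, 0.387 and 2.65 CPM in lateral replicates 1, 2 and 3 and 0 in dorsal ones, at least 66.3-fold lower (edgeR adjusted p = 0.0431), a call lost without lateral replicate 1. Of the features called, 49 and 72 differed by 2-fold or more. With the replicate number as a block edgeR called 392 features, 117 of them among the 123, while the calls of DN37984, DN40207 and DN39067 were lost. Of the alternatives run, 7 of 14 lost the call of DN37984, 4 of 14 that of DN40207 and 10 of 13 that of DN39067, and DN17121 lost its call without lateral replicate 1, 2 or 3 and with all libraries in one fit. Leaving out dorsal replicate 1, 2 or 3 or lateral replicate 1 gave 65, 61, 54 and 76 calls.

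At S9, 0 features were called between the petal types with edgeR. An unadjusted p under 0.05 was reached by 1139 features, where 1092 are 5% of those tested, and DESeq2 called 96. The S9 result rests on 2 libraries a group: without dorsal replicate 1 there were 365 calls and without lateral replicate 1 there were 2, in fits where the lone library is assumed to vary like the other groups.

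At S12, 201 features were higher in dorsal and 177 in lateral petals, of which 189 and 166 differed by 2-fold or more. DN44664_c0_g7_i1|m.57510 was at 19.1 ± 5.04 CPM (SD, n = 3) in dorsal petals against 0.0303 ± 0.0524 CPM in lateral petals, where a single count was recorded, a ratio of 672 with a 95% counting interval of 120 to 26500 (edgeR adjusted p = 1.48e-06). DN33661_c0_g1_i1|m.13125 was at 33.4 ± 6.4 against 0.133 ± 0.159 CPM, a log2 difference of 7.78 ± 1.04 (SE, edgeR adjusted p = 0.000276). DN29371_c0_g1_i1|m.8200 was at 2.73 ± 1.16 CPM in lateral petals and 0 in dorsal ones, at least 50.6-fold lower in dorsal petals (edgeR adjusted p = 0.0181). DN35837_c0_g1_i1|m.16328 was at 0.286, 6.02 and 1.73 CPM in lateral replicates 1, 2 and 3 and 0 in dorsal ones, at least 55.6-fold lower (edgeR adjusted p = 0.0172, and 0.0624 without lateral replicate 2). The 10 petal-enriched features, a set defined over all wild-type organs and so partly on these libraries, lay toward the dorsal side as a set, with 2 higher and 1 lower (limma camera adjusted p = 0.000172, and adjusted p = 0.0202 with an estimated correlation). Leaf-enriched features lay the same way with 1 of 29 called (camera adjusted p = 3.66e-06, and adjusted p = 0.237 with an estimated correlation), as did carpel-enriched features with 5 higher and 1 lower of 102 measured (camera adjusted p = 0.00187, and adjusted p = 0.334 with an estimated correlation). Sepal-enriched features lay toward the lateral side with 10 of 79 lower and 2 higher in dorsal petals (camera adjusted p = 0.00526, and adjusted p = 0.381 with an estimated correlation), and so did bract-enriched features with 4 of 40 lower and 0 higher (camera adjusted p = 0.0154, and adjusted p = 0.215 with an estimated correlation). Stamen-enriched features did not stand apart (camera adjusted p = 0.454). Leaving out dorsal replicate 2 or 3 or lateral replicate 1, 2 or 3 gave 195, 170, 178, 205 and 172 calls in place of 378. Of the alternatives run, DN44664 and DN33661 were called in all 14. DN29371 lost its call in 7 of 14, with the replicate block, with thinned libraries and without dorsal replicate 1, 2 or 3 or lateral replicate 1 or 3, and DN35837 in 5 of 13, with thinned libraries and without dorsal replicate 1, 2 or 3 or lateral replicate 2.

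At S16, 902 features were higher in dorsal and 369 higher in lateral petals, 71.0% on the dorsal side. This count of 1271 was the highest of the 4 stages when all petal libraries shared the estimate of spread, though not when only the compared groups did (504 at S16 against 1187 at S12). Differences of 2-fold or more numbered 842 and 314. DN42196_c0_g2_i12|m.34456 was at 111 ± 61.2 CPM (SD, n = 3) in dorsal petals and at 0 counts in the lateral libraries, at least 889-fold higher (edgeR adjusted p = 0.000673), and DN29871_c0_g1_i1|m.9074 was at 50.6 ± 23.3 CPM and 0, at least 382-fold higher (edgeR adjusted p = 0.00198). The lateral side was carried by a single library in both features named: DN45051_c1_g2_i1|m.62180 was at 0.369, 0.223 and 6.4 CPM in lateral replicates 1, 2 and 3 and at 0 in dorsal petals, at least 25.3-fold lower in dorsal petals (edgeR adjusted p = 0.00462), and DN43356_c2_g1_i2|m.42599 was at 0.615, 0.111 and 8.35 CPM against 1 count in dorsal petals, a ratio of 98.2 with a 95% counting interval of 16.9 to 3950 (edgeR adjusted p = 0.0218). Lateral replicate 3 at S16 had 14692 features with a rounded count of 1 or more and dorsal replicate 3 had 18190. Sepal-enriched features lay toward the lateral side, with 9 of 79 lower in dorsal petals and 0 higher (camera adjusted p = 1.16e-08, 1.18e-09 with the replicate block, and adjusted p = 0.104 with an estimated correlation), while bract-enriched features with 4 of 40 lower and 2 higher were called only without the block (camera adjusted p = 0.0373, 0.063 with the replicate block, and adjusted p = 0.295 with an estimated correlation). Of 465 measured stamen-enriched features 28 were higher in dorsal petals and 0 lower, while the set as a whole did not stand apart from the other features (camera adjusted p = 0.97), nor did the petal-, carpel- and leaf-enriched sets (camera adjusted p = 0.42, 0.426 and 0.436). By fry, which does not set a set against the other features, the petal-enriched set had adjusted p = 0.00171, and the stamen-, carpel- and leaf-enriched sets 0.304, 0.166 and 0.847. With the replicate number as a block edgeR called 2082 features, 1391 higher and 691 lower in dorsal petals, 1191 of them among the 1271. Leaving out dorsal replicate 1 gave 815 calls, and both lateral-side features lost their calls without the libraries under 19000 features. DN43356 lost its call in 8 of 13 alternatives, lateral replicate 3 left out among them, while DN42196 and DN29871 were called in all 14.

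**Figure D1:**
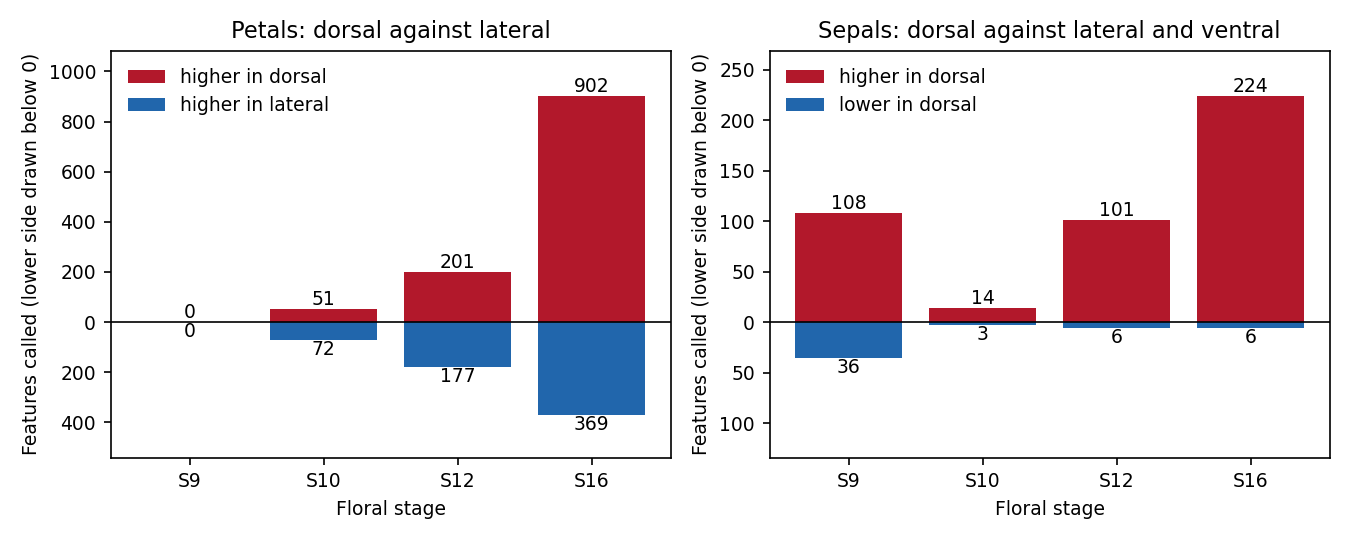
Number of features called (edgeR, adjusted p under 0.05) at each floral stage, in dorsal against lateral petals (left) and in dorsal spurred against lateral and ventral sepals (right). Bars above 0 count features higher in the dorsal organ and bars below 0 count features lower in it, from 0 and 0 at S9 to 902 and 369 at S16 in petals and from 108 and 36 at S9 to 224 and 6 at S16 in sepals.

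The features called at different stages overlapped in part. Of the calls at S10 and S12, 22 were higher in dorsal petals at both stages and 32 higher in lateral petals at both, where independent lists would share 0.469 and 0.584, and 1 had opposite directions. At S12 and S16, 77 and 61 were shared in direction (8.3 and 2.99 for independent lists) and 12 were opposite. Across S10, S12 and S16, 7 features were higher in dorsal and 8 in lateral petals at all 3 stages. A test of the change of the dorsal-lateral difference over stages, an interaction term, called 462 features, against 1099 with the replicate block, 1351 with DESeq2, 767 with voom weights, 895 without the libraries under 19000 features and 168 with all libraries in one fit. Of the 462, 313 had their largest difference at S16, 253 of them higher in dorsal petals, and 206 had differences of opposite sign at S12 and S16. Leaving out dorsal replicate 1 at S9 gave 850 interaction calls and leaving out dorsal replicate 1 at S16 gave 306.

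Development from S9 to S16 was followed within each petal type. In lateral petals 24 features changed from S9 to S10, 3453 from S10 to S12 (1708 rose, 1745 fell) and 6998 from S12 to S16 (3043 rose, 3955 fell). In dorsal petals the counts were 20, then 1877 (924 rose, 953 fell) and 7298 (3592 rose, 3706 fell). From S9 to S10, 23 rose and 1 fell in lateral petals, the latter DN45235_c0_g1_i13|m.65393 (log2 change of -8.34, SE 1.51, edgeR adjusted p = 0.0463). In dorsal petals 17 rose and 3 fell, the latter DN37219_c0_g1_i1|m.19188, DN42364_c0_g1_i1|m.35451 and DN47590_c0_g1_i1|m.101094 (log2 changes of -3.37, -3.04 and -2.19, SE 0.53, 0.5 and 0.36, each edgeR adjusted p = 0.0209). DESeq2 called 256 rising and 64 falling features in lateral petals over this step, and 160 and 118 in dorsal petals, where only the compared groups sharing the spread gave 0. Features changed in the same direction in both petal types: 655 rose and 793 fell in both from S10 to S12, with 4 opposite, where independent lists would share 72.3 and 76.2, and 2355 rose and 2841 fell in both from S12 to S16, with 64 opposite, where independent lists would share 501 and 671. Across features the log2 changes of the petal types correlated with Pearson's r of 0.15, 0.65 and 0.76 over the 3 steps (Spearman's rho 0.24, 0.68 and 0.76), with features not being independent replicates. Without lateral S9 replicate 1 or 2 or S10 replicate 2 the first lateral step gave 1, 8 and 4 calls, and without lateral S12 replicate 1 the second gave 1984. In dorsal petals the first step gave 679, 0, 12 and 0 calls without S9 replicate 1 or 2 or S10 replicate 1 or 2, and the second gave 1120, 1249, 1156 and 776 without S10 replicate 1, 2 or 3 or S12 replicate 1.

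Over the last step more sepal- and bract-enriched features rose than fell and more leaf- and carpel-enriched features fell than rose, with fewer sets called by camera with an estimated correlation than with a preset one. The sets were chosen partly on the petal libraries, so they are not independent evidence of direction. Shifts of the sepal- and leaf-enriched sets were not particular to petals. In lateral sepals the sepal-enriched mean went from 5.03 ± 0.26 at S12 to 6.63 ± 0.31 log2 CPM at S16 (SD, n = 3). In stamens it went from 2.05 ± 0.08 to 3.36 ± 0.98. The leaf-enriched mean went from 5.81 ± 0.01 to 3.26 ± 0.4 in lateral sepals and from 3.93 ± 0.18 to 1.9 ± 0.73 in stamens. In carpels it went the other way, from 5.24 ± 0.21 to 5.86 ± 0.43. From S12 to S16 in lateral petals 51 of 79 sepal-enriched features rose and 5 fell (camera adjusted p = 3.2e-16, and adjusted p = 0.0251 with an estimated correlation), and their mean level went from 2.48 ± 0.28 to 5.18 ± 0.16 log2 CPM (SD over libraries, n = 3 each). Of 40 measured bract-enriched features 18 rose and 3 fell (camera adjusted p = 1.02e-07, and adjusted p = 0.0202 with an estimated correlation). Of 29 leaf-enriched features 19 fell and 0 rose (camera adjusted p = 1.43e-05, and adjusted p = 0.276 with an estimated correlation), and of 102 measured carpel-enriched features 48 fell and 1 rose (camera adjusted p = 4.72e-07, and adjusted p = 0.13 with an estimated correlation). Of 465 stamen-enriched features 81 rose and 23 fell (camera adjusted p = 4.44e-05, and adjusted p = 0.34 with an estimated correlation). In dorsal petals 44 sepal-enriched features rose and 7 fell (camera adjusted p = 4.82e-10, and adjusted p = 0.0997 with an estimated correlation), 26 bract-enriched features rose and 1 fell (camera adjusted p = 4.05e-09, and adjusted p = 0.0202 with an estimated correlation), 25 leaf-enriched features fell and 0 rose (camera adjusted p = 1.98e-10, and adjusted p = 0.104 with an estimated correlation) 45 carpel-enriched features fell and 3 rose (camera adjusted p = 1.16e-08, and adjusted p = 0.104 with an estimated correlation) and 121 stamen-enriched features rose and 12 fell (camera adjusted p = 3.66e-06, and adjusted p = 0.326 with an estimated correlation). The 10 petal-enriched features went both ways, 4 up and 3 down in lateral petals and 4 up and 4 down in dorsal ones (camera adjusted p = 0.331 and 0.728, fry adjusted p = 0.00533 and 0.171). Sepal-enriched features also rose from S10 to S12, 26 in lateral petals against 2 that fell (camera adjusted p = 1.16e-08, and adjusted p = 0.104 with an estimated correlation) and 19 in dorsal petals against 1 (camera adjusted p = 3.02e-07, and adjusted p = 0.13 with an estimated correlation). Carpel-enriched features fell over that step, 48 in lateral petals against 3 that rose (camera adjusted p = 6.05e-15, and adjusted p = 0.0254 with an estimated correlation) and 34 in dorsal petals against 0 (camera adjusted p = 2.48e-16, and adjusted p = 0.0244 with an estimated correlation).

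Features highest in one organ kind over the whole series were collected by a fixed rule, at least 4-fold above each other kind with adjusted p under 0.05. The rule gave 29 leaf-enriched, 44 bract-enriched, 79 sepal-enriched, 10 petal-enriched, 529 stamen-enriched and 121 carpel-enriched features of 23573 tested. DN35623_c0_g1_i1|m.16209 was at 3030 ± 1240 CPM in leaves (SD, n = 4) and 408 in bracts, the next organ. DN43459_c3_g1_i3|m.43608 was at 4220 ± 1660 CPM in bracts (SD, n = 4) and 615 in sepals, and DN36067_c0_g1_i1|m.17077 at 1820 ± 421 and 966. DN37047_c0_g1_i1|m.19017 and DN42876_c0_g5_i1|m.39052 were at 295 ± 488 and 279 ± 286 CPM in petals (SD over 22 libraries of 4 stages) and at 78.3 and 38.7 in stamens. In stamens DN46291_c1_g1_i4|m.81075 was at 8610 ± 8950 CPM (SD over 11 libraries) and 253 in petals, and DN45183_c0_g1_i6|m.64444 at 7850 ± 11300 and 53.5 in sepals. In carpels DN40433_c0_g2_i2|m.28114 was at 1900 ± 923 CPM (SD over 11 libraries) and 709 in stamens, and DN36622_c0_g1_i1|m.18158 at 1310 ± 3160 and 7.1 in sepals. The level of DN36622 rests on replicate 3 at S16 with 10600 CPM, and without that library its mean in carpels was 604 CPM. In sepals DN46111_c2_g2_i1|m.79149 was at 1360 ± 841 CPM (SD over 33 libraries) and 457 in petals. It lost its place in the set in 4 of 8 alternatives, with no filter, with the replicate block and without replicate number 1 or 3. DN35623 and DN45183 lost theirs without replicate number 2, and DN36067 and DN37047 without the libraries under 19000 features. The rule compares group means on the log scale, and the sepal-enriched DN41573_c0_g1_i1|m.32174 had an arithmetic mean of 8400 ± 14400 CPM in sepals (SD), below the 9890 in petals. With the replicate number as a block the bract set held 68, the petal set 6 and the stamen set 242. Without replicate number 2 the sets held 4, 15, 44, 5, 264 and 56 features in the order above, without replicate number 1 the leaf set held 9, and without replicate number 4 the bract set held 21.

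The question of what marks the lateral petals themselves was asked with a similar rule, at least 2-fold above dorsal petals and above each other organ kind, which left 5 features. DN48556_c0_g3_i1|m.118171 was at 508 ± 460 CPM in lateral petals (SD over 11 libraries) and 16.5 in dorsal petals, the next organ by its mean over stages. At S10 lateral sepals (44.8 ± 57.1 CPM) and carpels (33.1 ± 20.1) lay above dorsal petals (14.8 ± 7.59), and at S9 dorsal petals (45 ± 24.5) lay above both. It stood at 812 ± 402 CPM at S9 (SD, n = 2), 992 ± 40.7 at S10, 217 ± 45.5 at S12 and 1.27 ± 1.13 at S16 (SD, n = 3). DN45352_c1_g2_i2|m.67254 followed a like course, with 109 ± 31.1, 134 ± 77.1, 92.4 ± 40.8 and 0.488 ± 0.563 CPM at the 4 stages. DN38252_c0_g1_i1|m.21453 was highest at S10 with 511 ± 262 CPM and lay at 22.2 ± 13.5 at S16, below the 56.6 ± 29.4 CPM of stamens at that stage. DN47476_c5_g1_i2|m.99263 reached 6.44 ± 4.58 CPM at S10 and lay at 0.0736 ± 0.127 at S16. DN39067_c0_g1_i3|m.23598 did not change steadily, with 0.651 ± 0.379, 3.77 ± 4.2, 0.356 ± 0.348 and 7.59 ± 4.71 CPM at the 4 stages. Single libraries at S10 ran from 3.3 to 11.7 CPM for DN47476 and from 0.361 to 8.46 CPM for DN39067, so both means depend on the highest library. In the silencing libraries DN48556 was at 31.3 and 52.3 CPM in ans and at 11.3 and 92.1 CPM in ans-lmi1. With the replicate number as a block the rule left 1 feature, DN38252. Without replicate number 2 it left 0 features and without replicate number 1 it left 3. Without the libraries under 19000 features it left 9.

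**Figure D2:**
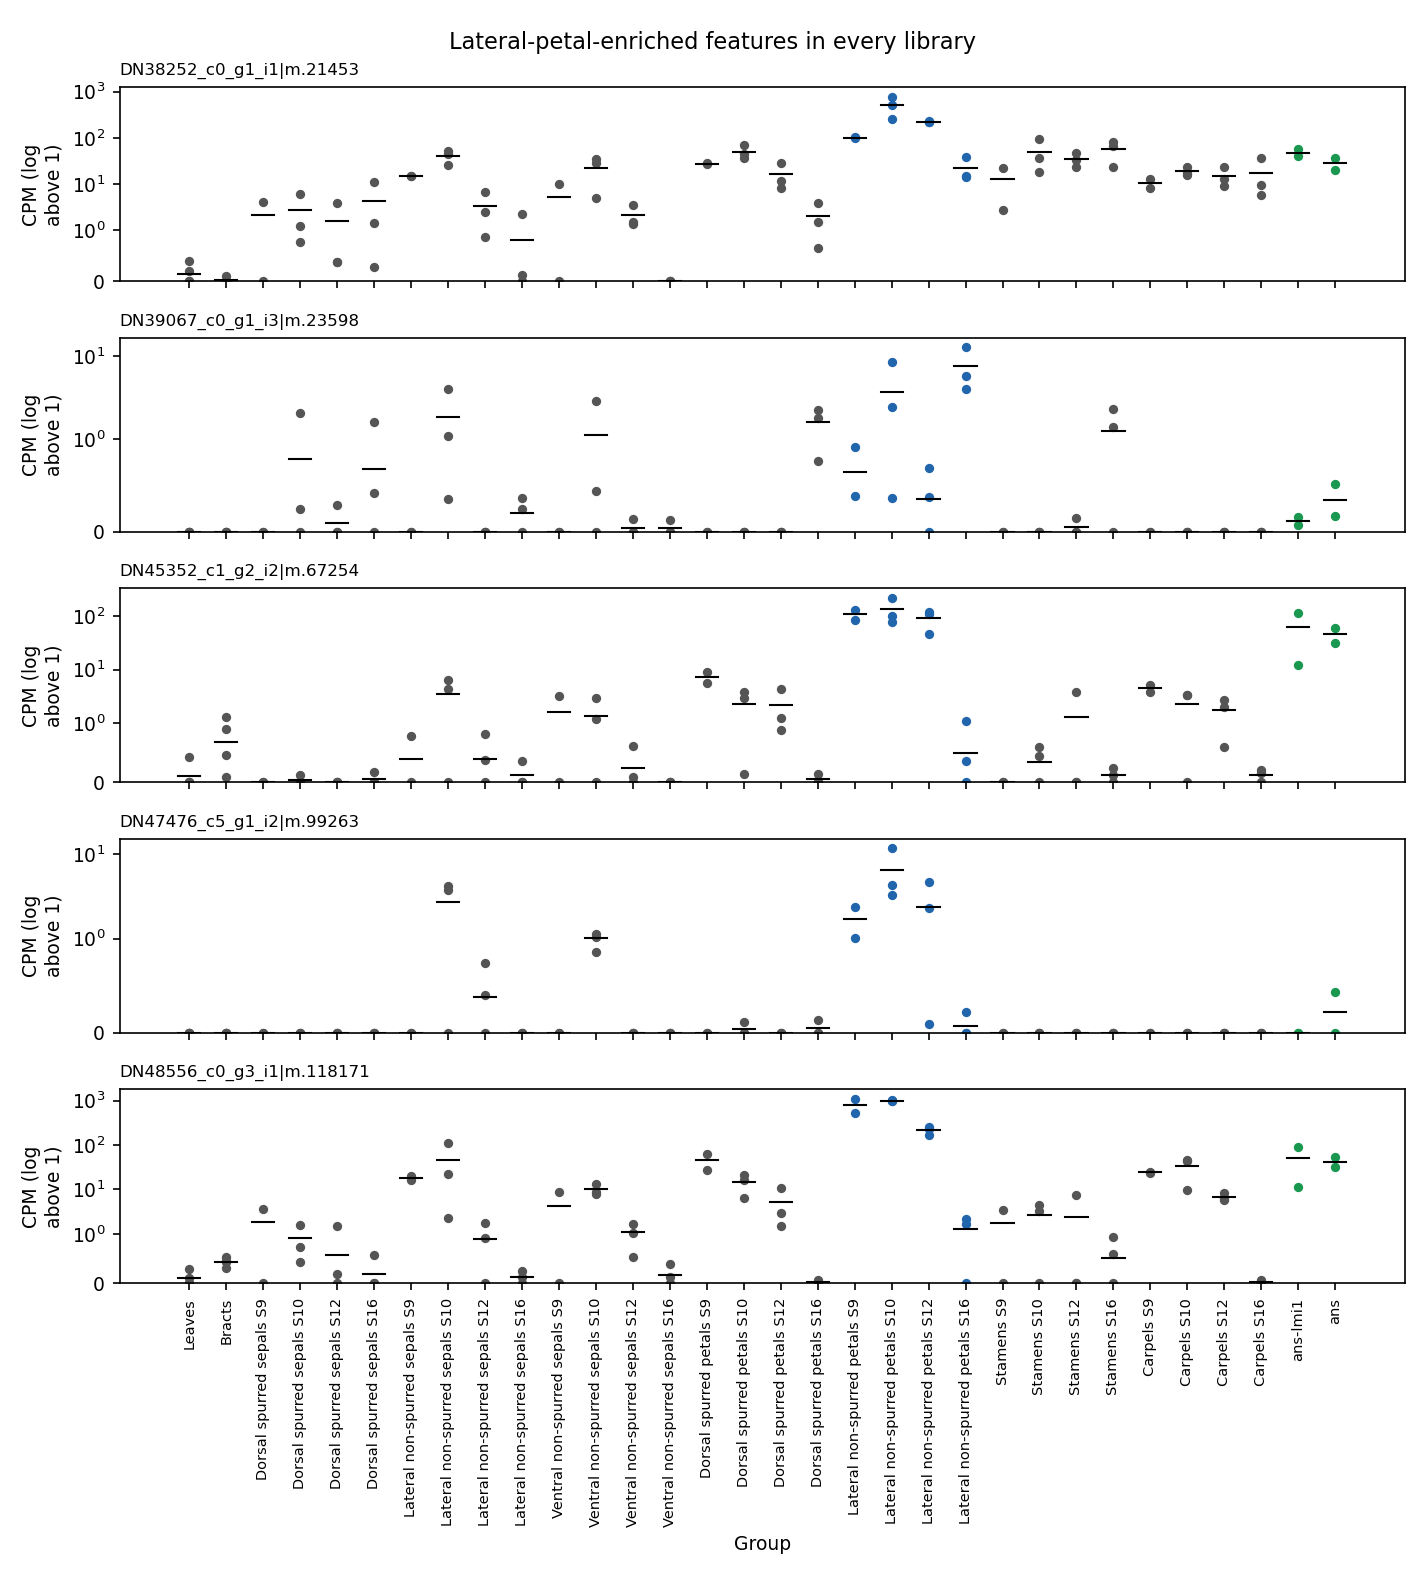
Level of the 5 lateral-petal-enriched features in each of the 89 libraries, in CPM on an axis that is logarithmic above 1 and linear below. Points are libraries, bars are group means, blue marks lateral petals and green the silencing libraries, with DN48556 between 958 and 1040 CPM at S10 and between 0 and 2.16 CPM at S16 in lateral petals.

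The same spurred against non-spurred contrast was made in the outer whorl, with the dorsal spurred sepal against the mean of lateral and ventral sepals. The features called were mostly higher in the spurred sepal. At S10, 14 were higher and 3 lower, the latter DN43915_c1_g2_i2|m.48582, DN45049_c1_g2_i3|m.62460 and DN45809_c3_g2_i1|m.74056 (log2 differences of -1.5, -1.17 and -1.11, SE 0.3, 0.24 and 0.22, edgeR adjusted p = 0.0329, 0.0491 and 0.0289). At S12 101 were higher and 6 lower, and at S16 224 were higher and 6 lower, of 21673 tested. At S9, 108 were higher and 36 lower, calls that ended when only the compared groups shared the spread (0) and nearly so with voom weights (2). With only the compared groups the S16 count was 22 and with voom weights 1359. With the replicate number as a block the calls numbered 132 at S10 (80 higher, 52 lower), 210 at S12 (173 and 37) and 361 at S16 (311 and 50). DESeq2 gave 563 higher and 402 lower at S9 and 58 and 23 at S10. Calls at S12 and S16 shared 27 features higher in the spurred sepal, where independent lists would share 1.04. The S9 count went to 75, 296, 5764 and 61 without dorsal replicate 1, dorsal replicate 2, lateral replicate 2 or ventral replicate 2, where the lone library left in that group is assumed to vary like the others. Elsewhere the counts were 8, 6, 8, 11 and 11 at S10 without dorsal replicate 1, 2 or 3, lateral replicate 1 or ventral replicate 1, 49 and 70 at S12 without dorsal replicate 3 or lateral replicate 2, and 125, 115 and 147 at S16 without dorsal replicate 1 or 3 or lateral replicate 2.

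Lateral and ventral sepals, both without a spur, were compared with each other. At S10 edgeR called 0 features (324 at an unadjusted p under 0.05, 6 with DESeq2) and at S12 also 0 (135 unadjusted, 10 with DESeq2). At S16 it called 1, DN46793_c1_g3_i1|m.88554, at 4.86 ± 5.23 CPM in lateral and 0.161 ± 0.14 CPM in ventral sepals (SD, n = 3), a log2 difference of 4.68 ± 0.7 (SE, edgeR adjusted p = 0.0052). Its level rests on lateral replicate 3, with 1.64, 2.06 and 10.9 CPM in lateral replicates 1, 2 and 3. The call was lost without lateral replicate 3 or ventral replicate 1 or 3. DESeq2 called 122 features at S16, 103 higher and 19 lower in lateral sepals, the replicate block gave 8 calls and only the compared groups gave 0. At S9, 11 features were higher and 141 lower in lateral sepals, against 308 and 845 with DESeq2, 0 with only the compared groups sharing the spread and 0 with voom weights. The libraries behind that comparison stood apart from each other: the lateral sepal libraries at S9 correlated at 0.67 across features, the lowest of any pair within a group, and replicate 1 had 9879 features detected. Without lateral replicate 1 the S9 count was 37 and without lateral replicate 2 it was 6968, in fits where the lone lateral library is assumed to vary like the other groups. At S16 the count was 5, 4 and 0 without lateral replicate 1, 2 or 3, and 0, 3 and 0 without ventral replicate 1, 2 or 3.

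Whether the spurred position is marked by the same features in both whorls was asked by setting the dorsal-minus-lateral difference in petals beside the dorsal-minus-non-spurred difference in sepals, which share no library. Pearson's r across 20966 features was 0 at S9, 0.2 at S10, 0.11 at S12 and 0.05 at S16 (Spearman's rho 0.02, 0.25, 0.16 and 0.05), with a jackknife SD over replicate numbers of 0.021, 0.023, 0.044 and 0.049. Groups at S9 have no replicate 3, so leaving out that number removed no library of the stage. The 0.021 is therefore not comparable with the SD of the later stages. Over the features called in either comparison r was 0.23, 0.58, 0.3 and 0.05, and with no filter on low counts it was 0.12 at S10. At S12, 15 features were higher and 2 lower on the dorsal side in both whorls and 12 were called in opposite directions, where independent lists would give 0.935, 0.0504 and 0.896. At S16, 45 were higher in both, 5 lower in both and 23 opposite, where independent lists would give 9.21, 0.106 and 4.17. Without replicate number 2 or 3 r at S10 was 0.15 in each case, and without the libraries under 19000 features r was 0.14, 0.05 and 0.11 at S10, S12 and S16. At S12 it was 0.05 without replicate number 2 and at S16 0.12 without replicate number 3.

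Leaves and the bracts beneath the flower buds differed in 6972 of 18368 features, 3399 higher in leaves and 3573 higher in bracts (edgeR, 4 libraries against 4). Of these 1738 and 1804 differed by 2-fold or more, and the median size of a called difference was 1.01 on the log2 scale. DN35623 and DN42647_c0_g1_i1|m.37444, the most abundant leaf-enriched features, were at 3030 ± 1240 and 1240 ± 354 CPM in leaves (SD, n = 4) against 408 and 246 in bracts. The mean of the bract-enriched set was 5.45 ± 0.46 log2 CPM in bracts and 1.58 ± 0.42 in leaves (SD, n = 4 each). In each of the 8 fits with a library left out the count stayed within 1.5 times the full one, between 5208 and 7011, while with all libraries in one fit it was 1033.

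The silencing experiment used a virus-based method that lowers the transcript of a chosen gene, and compared ans-lmi1 with ans, which the file headers call mock. ANS is a name for anthocyanidin synthase, an enzyme of pigment synthesis, and LMI1 in other plants for a homeodomain transcription factor. Since the files do not pair IDs with names, the level of the targeted transcripts was not analysed here. The labels disagree on these libraries: the tissue is given as lateral sepals while the design text speaks of petals at stage 12, and the genotype reads LMI1 knockdown for ans-lmi1 replicate 1 and LMI2 knockdown for replicate 2. They were grouped by title. Across features the 4 libraries correlated best with the mean of wild-type lateral petals at S12 (Pearson's r 0.949, 0.955, 0.937 and 0.961 for ans replicates 1 and 2 and ans-lmi1 replicates 1 and 2), above lateral sepals at S12 (0.918, 0.919, 0.913 and 0.923). Features higher in dorsal petals at S12 had means of 3.14 to 3.43 log2 CPM in them, where wild-type lateral petals at S12 lay between 3.19 and 3.44 and dorsal petals between 5.51 and 5.68. Lateral sepals at S12 had 3.42 ± 0.19 (SD, n = 3), so this set does not separate lateral petals from lateral sepals. The match with lateral petals at S12 was not full. DN38252 was at 27.8 ± 11.3 CPM in ans and 47.8 ± 11.3 in ans-lmi1 (SD, n = 2). Lateral petals had 221 ± 5.93 and lateral sepals 3.3 ± 2.99 CPM at S12 (SD, n = 3). In the same order, DN48556 was at 41.8 ± 14.9, 51.7 ± 57.2, 217 ± 45.5 and 0.894 ± 0.88 CPM. Bract-enriched means were 2.36, 2.5, 1 and 2.72 log2 CPM, and petal-enriched means 4.13, 4.25, 4.69 and 0.6.

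Between ans-lmi1 and ans 0 of 18757 features were called with edgeR (smallest adjusted p = 0.255). An unadjusted p under 0.05 was reached by 1373, where 938 are 5% of those tested, and DESeq2 called 122, 75 higher and 47 lower in ans-lmi1. The 2 ans-lmi1 libraries lay on either side of the ans libraries in features that change with stage: the mean of the features rising from S12 to S16 in lateral petals was 4.16 and 3.44 log2 CPM in ans-lmi1 replicates 1 and 2 and 3.73 and 3.74 in ans, and that of the falling features 3.73 and 4.23 against 4.06 and 4.03. None of 11 feature sets was called by camera (smallest adjusted p = 0.428, smallest adjusted p = 0.913 with an estimated correlation), among them the features higher in lateral petals at S12 (162 measured, median log2 difference 0.03) and those higher in dorsal petals (164 measured, median 0.1). By fry's mixed test, which asks whether a set's members change in either direction, the stamen-enriched set had adjusted p = 0.0223. The mean of that set was low in these libraries, -0.06 ± 0.03 log2 CPM in ans and 0.05 ± 0.36 in ans-lmi1 (SD, n = 2 each). Adjusted over the list alone, 3 and 1 of the features higher in lateral petals rose and fell and 2 bract-enriched features rose, against 0 over all features. The effect correlated with the dorsal-lateral difference at S12 at r = 0.04 across 18611 features (Spearman's rho 0.08). Without replicate number 2, in the petals too, r was 0.13. There the effect was a plain log2 CPM difference between the 2 silencing libraries left, not an edgeR fold change, so these values are not alike. Without ans-lmi1 replicate 1 or 2 edgeR called 31 and 86 features and camera 3 and 4 sets, in fits where the lone library is assumed to vary like its counterpart group, and without ans replicate 2 camera called 1 set.

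**Figure D3:**
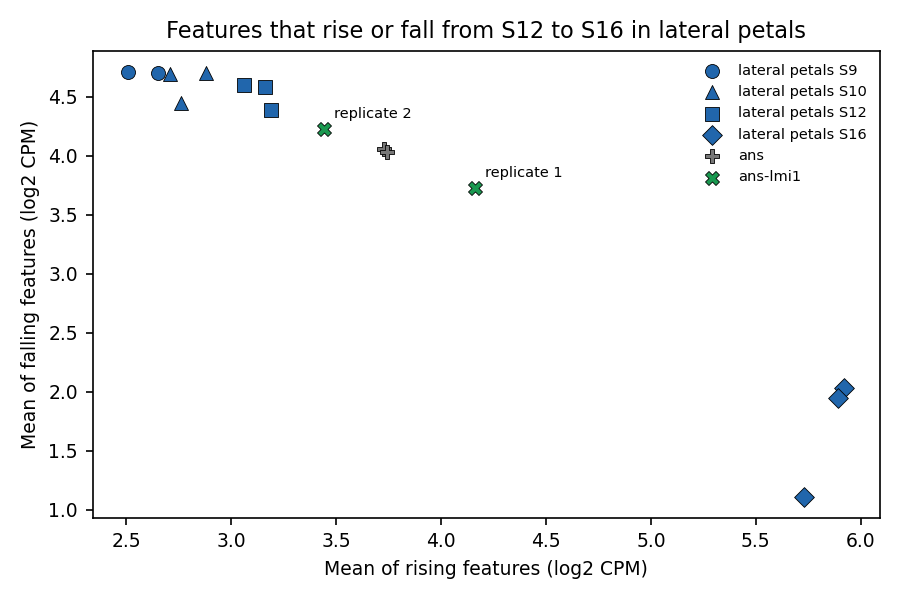
Mean level in log2 CPM of the features rising from S12 to S16 in lateral petals (horizontal axis) against those falling (vertical axis), in each lateral petal library and each silencing library. Points are single libraries. The ans libraries lie at 3.73 and 3.74 on the horizontal axis, between ans-lmi1 replicate 2 at 3.44 and replicate 1 at 4.16.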

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

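The tests of explanations in this part were chosen after the results were seen. A change of the dorsal-lateral petal difference with stage was called for 462 features by a test of the difference between stages itself, 313 of them with their largest difference at S16. Leaving out dorsal replicate 1 at S9 gave 850 and leaving out dorsal replicate 1 at S16 gave 306, while the replicate block gave 1099, DESeq2 1351 and all libraries in one fit 168. In leaves and bracts, the only groups with 4 or more libraries, 10 checks of totals, detected features and abundant features found no library that stood apart by Dixon's ratio test.

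At S16 71.0% of the 1271 features called between petal types were higher in dorsal petals, between 66.8% and 78.2% with any 1 S16 petal library left out and 63.1% with DESeq2. Without the libraries under 19000 features the share was 66.3%, and with petal libraries thinned to one total it was 68.2%, which argues against few detected features and greater depth of the dorsal libraries as the whole cause. Leaving out stamen-enriched features gave 70.3%, but with 28 of them among the calls this could hardly move the share, so stamen material cannot be told apart from a difference between petals by this test. A difference between the petal positions, which the design names, stays open too and was not tested.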

How the results depend on the processing

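Alternatives chosen after the data were seen were the fits without libraries under 19000 features, voom with sample quality weights, thinning of petal libraries and the developmental covariate. Among the recomputed log2 differences of named features, and correlations larger than their jackknife SD, none reversed in sign. Counts of calls and membership of a set could not reverse. Of the 30 named features 11 kept their call or place in a set under each alternative run and 19 lost it under at least 1. Counts of calls were less stable. With thinned petal libraries all 11 petal counts stayed within 1.5 times the reported ones. With no filter on low counts 30 of 33 results did, and with DESeq2 14 of 33, the other 19 all being higher. In data simulated from edgeR's own dispersions DESeq2 also gave more false calls than edgeR. Except where stated, the cause of a change was not tested. Depth limits what could be called at 0 counts, where a fold is a lower bound.

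With DESeq2, dorsal against lateral petals gave 96, 429, 792 and 2260 calls at S9, S10, S12 and S16, the step from S9 to S10 gave 320 in lateral and 278 in dorsal petals, the step from S10 to S12 gave 3170 in dorsal petals, and the change of the petal difference with stage gave 1351. Dorsal against non-spurred sepals gave 965, 81, 231 and 517 at the 4 stages, and lateral against ventral sepals 1153, 6, 10 and 122. The silencing comparison gave 122, and the leaf-enriched and petal-enriched sets held 50 and 16. With no filter, S9 to S10 in dorsal petals gave 35, the silencing comparison 1, and the petal-sepal correlation at S10 was 0.12.

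With voom weights, dorsal against lateral petals gave 4, 353, 2273 and 4030 calls, the lateral steps 223, 6690 and 12531, the dorsal steps 10, 5419 and 11863, and the change with stage 767. Dorsal against non-spurred sepals gave 2, 1221, 1059 and 1359, and lateral against ventral sepals 0, 1, 17 and 55. The weight was 0.03 for ventral sepal replicate 3 and 0.09 for lateral petal replicate 3, both at S16.

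Without libraries under 19000 features, dorsal against lateral petals gave 8, 374 and 1242 calls at S9, S10 and S12, the step from S9 to S10 gave 183 in lateral petals, the step from S10 to S12 gave 6322 in lateral and 5616 in dorsal petals, and the change with stage 895. Dorsal against non-spurred sepals gave 251, 247 and 393 at S10, S12 and S16, and lateral against ventral sepals 1 and 3 at S10 and S12. Leaf-, bract- and sepal-enriched sets held 71, 100 and 140 features and the lateral-petal set 9. The petal-sepal correlation was 0.14, 0.05 and 0.11 at S10, S12 and S16. At S9 in sepals the alternative could not be run, since all sepal libraries of that stage fall under the minimum.

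With only the compared groups sharing the spread, which means fewer libraries, dorsal against lateral petals gave 208, 1187 and 504 calls at S10, S12 and S16. S9 to S10 in dorsal petals gave 0 and S10 to S12 in dorsal petals 4235. Dorsal against non-spurred sepals gave 0, 118, 307 and 22 at the 4 stages, and lateral against ventral sepals 0 at S9 and 0 at S16. With all libraries in one fit, dorsal against lateral petals gave 2, 17, 102 and 515, the lateral steps 3, 1344 and 4336, the dorsal steps 1, 596 and 4544, and the change with stage 168. Dorsal against non-spurred sepals gave 620, 30 and 352 at S9, S10 and S16, lateral against ventral sepals 418 at S9 and 19 at S16, leaves against bracts 1033 and the silencing comparison 1. For leaves against bracts and the silencing comparison the reported fit already holds only the groups compared, for the change with stage it needs all petal groups, and a pseudocount does not apply to counts, so those alternatives were not run.

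With the replicate number as a block, counts rose to 20, 392, 858 and 2082 for dorsal against lateral petals, to 42 and 31 for S9 to S10 in lateral and dorsal petals, to 1099 for the change with stage, to 329, 132, 210 and 361 for dorsal against non-spurred sepals and to 321 at S9 and 8 at S16 for lateral against ventral sepals. The bract-enriched set held 68, the petal-enriched 6, the stamen-enriched 242 and the lateral-petal set 1. Where the numbers pair the libraries the block moved no other count of a comparison by over 1.5 times, and among the set tests of dorsal against lateral petals, adjusted over these tests alone, it ended the call of bract-enriched features at S16 (adjusted p = 0.063) and, where libraries share only a number, at S12 (adjusted p = 0.0547). Elsewhere libraries share only a number: correlations of same-numbered libraries were 0.02 to 0.27 for dorsal against lateral petals at S12, 0.07 at S9 with 2 pairs, -0.13 to 0.29 over the steps, 0 to 0.07 for dorsal against non-spurred sepals at S9, -0.01 for lateral against ventral sepals at S9 and 0.12 with 2 pairs in the silencing comparison, where the block gave 0 calls. In dorsal against non-spurred sepals at S9 each library correlated best with its own number. With 2 libraries a group the deviations mirror each other, so any correlation above 0 gives that result, and it does not bear on pairing. In petals at S12 and over the steps libraries did not each correlate best with their own number.

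A developmental covariate in the silencing comparison, with 1 residual degree of freedom, gave 9 calls. Spearman's correlation between petals and sepals was 0.25 at S10 and 0.16 at S12, and over features called in either comparison Pearson's was 0.23, 0.58 and 0.3 at S9, S10 and S12.

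Leaving out 1 library at a time, counts ranged from 0 to 365, 54 to 97, 170 to 299 and 815 to 1341 for dorsal against lateral petals, from 1 to 34, 1984 to 3102 and 5587 to 7233 for the lateral steps, from 0 to 679, 776 to 1497 and 5761 to 7163 for the dorsal steps, and from 306 to 850 for the change with stage. They ranged from 61 to 5764, 6 to 16, 49 to 91 and 115 to 248 for dorsal against non-spurred sepals, from 37 to 6968 at S9 and 0 to 5 at S16 for lateral against ventral sepals, with 0 at S10 and S12, and from 0 to 86 in the silencing comparison, where 0 to 4 sets were called. Without 1 replicate number the leaf-, bract-, sepal-, petal-, stamen- and carpel-enriched sets held 4 to 37, 15 to 36, 44 to 72, 5 to 10, 264 to 484 and 56 to 105 features and the lateral-petal set 0 to 5. Petal-sepal correlations ranged from -0.02 to 0.02, 0.15 to 0.18, 0.05 to 0.13 and 0.04 to 0.12. That of the silencing effect with the petal difference ranged from 0.06 to 0.13, with the effect taken as a log2 CPM difference of single libraries. Libraries whose removal moved a count by over 1.5 times are named beside each comparison.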

Other observations

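The tests of explanations of the silencing libraries were chosen after the results were seen. On an axis of 511 features that differ at least 4-fold between lateral sepals (0) and lateral petals (1) at S12, lateral petals at S16 lay at 0.54, 0.55 and 0.6, while lateral sepals at S16 lay at -0.03, -0.01 and 0.04. Dorsal petals at S12 lay at 0.89, 0.92 and 0.9. Outside the petals, the lateral-petal-enriched DN38252_c0_g1_i1|m.21453 was at 12.6 ± 13.9 CPM (SD, n = 2) in stamens at S9 and at 50 ± 40.5, 35.1 ± 12.1 and 56.6 ± 29.4 CPM (SD, n = 3) at S10, S12 and S16. The stamen libraries at S10 ran from 17.7 to 95.4 CPM, so that mean depends on the highest library.

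The silencing libraries carry a tissue label of lateral sepals and a design text that speaks of petals. On the axis above they lay at 0.85 and 0.9 for ans and 0.83 and 0.92 for ans-lmi1, with a mean of 0.88. Lateral sepals would lie near 0, which argues against that label for these libraries. That they are petals, as the design text has it, stays open as a hypothesis tested on the same data.

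No feature was called between ans-lmi1 and ans with edgeR, while 1373 had an unadjusted p under 0.05 and DESeq2 called 122. The smallest total of the 4 libraries was 12452930 counts, above the wild-type median of 7705354, which argues against low depth. It does not argue against low power: the fit had 2 libraries a group and 2 residual degrees of freedom. In simulated counts it recovered 23.9% of the features changed by 2-fold. Across 18611 features the difference of ans-lmi1 replicate 1 from replicate 2 correlated at 0.54 with the change from S12 to S16 in wild-type lateral petals, and that of the ans replicates at 0.01. A candidate explanation for the lack of calls is that the ans-lmi1 libraries differ in developmental position. A small effect of the silencing, or a difference between the 2 genotypes the labels give, stays open and was not tested.

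Other splits of the same libraries were counted for each comparison of 3 or more libraries a group, with tests written before their counts were seen. Dorsal against lateral petals gave 123, 378 and 1271 calls at S10, S12 and S16 and at most 1, 0 and 13 in another split, the steps from S10 to S12 gave 3453 and 1877 against 0 and 0, and those from S12 to S16 gave 6998 and 7298 against 0 and 1. Lateral against ventral sepals gave 0, 0 and 1 against 0, 0 and 8, with 10, 10 and 5 of the 10 splits giving a count as large. These comparisons have 10 splits each, too few for a share under 0.05. Leaves against bracts gave 6972 against 0, with 35 splits counted and 1 as large, a share under 0.05 over all splits, while those that part each pair of a replicate number are too few for such a share. Dorsal against non-spurred sepals gave 17, 107 and 230 at S10, S12 and S16. In 21 splits drawn without regard to replicate number, another reached at most 1, 216 and 44, with 1, 2 and 1 splits as large. The split with 216 parts the 3 replicate 3 libraries from the rest, so the samples have a structure by replicate number, and with the number as a block the S12 count was 210. Since the numbers pair these libraries, splits that take 1 library of each number were counted too, a test added after the others were seen. Of 27 such splits at each stage 1 was as large, the real one, and another reached at most 0, 0 and 17. That share is under 0.05 at each stage but is the smallest that 27 splits allow. It was not adjusted over the 3 stages, so it does not exclude chance. For the organ-enriched sets 100 labellings of the libraries, the real one included, were counted with limma on log2 CPM, which gives other sizes than edgeR. The leaf, bract, sepal, petal, stamen, carpel and lateral-petal sets held 40, 83, 84, 13, 733, 109 and 11 features and at most 26, 31, 0, 0, 0, 0 and 1 in another labelling, 1 labelling of each being as large. Labels were shuffled over all wild-type libraries without regard to replicate number, which removes every organ and stage difference at once. The counts therefore bear on the limma sets as wholes, not on single members or on the sets edgeR gave.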
